A study of Mus musculus with 6 samples.

How the data were processed

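The series measured chromosome contacts by Hi-C in mouse embryonic fibroblasts of a 129xCast hybrid background. In Hi-C, chromatin is crosslinked and cut, ends that lie close together are ligated, and the joined fragments are sequenced in pairs. Here the cut was made with HindIII and ligation took place in dilution, per the labels' protocols. The labels list 6 samples in 1 group, from 2 embryos with 3 technical replicates each. Sequence differences between the parental genomes allow an end that covers such a difference to be assigned to an allele, and the series describes the assay as allele-specific.

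The values are a balanced contact signal per pair of 1 Mb bins, pooled by the authors into 1 matrix and deposited as a sparse table with a key of bin positions. The submitters' processing notes name HiC-Pro 2.7.8, bedtools and the mouse build mm9, without roles or settings. The aligner, the read filters and which of the libraries entered the pool are not given in the sources used here. The name of the deposited table combines CAST and 129 with codes that fit pairs of unlike alleles. It was therefore read as holding contacts with one end on a Cast chromosome and the other on a 129 chromosome. The labels do not state this reading. The values show almost no decline with distance within a chromosome, unlike a map of all contacts. If the reading holds, values within a chromosome are contacts between homologs. The text calls them same-chromosome contacts. The table is symmetric, so the 129 and Cast ends of a contact cannot be separated, and differences between the alleles were not analysed here.

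Balancing scales every bin to about the same sum, with a median row sum of 1521 over the 2573 bins that hold a value. Of the 2666 bins in the key, 93 held none, among them all 16 bins of chromosome Y. Each balanced value was found to be a whole number of contacts times a factor for each of its bins. All 1365118 listed pairs of different bins came out whole within 0.01. The recovered counts sum to 1955524 contacts between different bins and 2884 within a bin. A single contact underlies 67.7% of the listed pairs, so the depth is low for any single pair of bins.

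Bins with fewer listed partners on other chromosomes than 50% of the median of 1087 were left out, which kept 2341 bins. Pairs of kept bins that were not listed counted as 0. Observed/expected values of the balanced signal are means over pairs divided by the mean over all pairs of bins on different chromosomes. For recovered counts the expected value was the product of bin factors fitted to each bin's total on other chromosomes. The main setting used the balanced signal, and counts gave 95% Poisson or exact binomial intervals. These intervals cover counting error only, since PCR copies are not independent molecules and the map has no replicate. No test therefore compares samples, and the spread over chromosomes describes this map.

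Comparisons covered the share of same-chromosome contacts, the slope of log10 contact on log10 distance over 2 to 50 Mb, contacts per pair of chromosomes, X beside the 19 autosomes, the 10 Mb at chromosome ends, the chromosomes that carry ribosomal DNA in laboratory mice, the first eigenvector of the trans contact profiles, and single pairs of bins. Positions were described as percentiles among 10000 permutations of chromosome labels or 10000 sets of randomly placed windows. Pairs of bins were tested against counting noise with a 1-sided Poisson test and Benjamini-Hochberg adjustment over 2594953 pairs. A further 100 maps with no structure were drawn from the bin factors. These comparisons, their settings and the rule for named items were fixed before the data were examined. The rule names the 3 highest or lowest chromosomes and X, the 5 highest and 5 lowest chromosome pairs, the 10 pairs of bins with the highest observed/expected (1 per pair of chromosomes) and the 10 bins of highest mean trans contact (1 per 5 Mb). Alternatives were recovered counts, no bin filter, a filter at 80%, listed pairs alone, trans values capped at the 99.9th percentile, each chromosome left out, and settings specific to a comparison. Listed pairs alone drop every zero, so their mean rises where bins hold few contacts and does not measure contact frequency alone.

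Gene lists fixed in advance were not analysed here, because gene positions on mm9 were not used here. The steps were tested on simulated data. Counts were recovered for 100% of 1320171 simulated pairs, and an implanted ratio of 1.5 at 1 Mb came back as 1.48. Among 2594953 simulated pairs of bins, those raised 4 times were called in 1.49% of 67 cases, those raised 8 times in 19.4% of 67 and those raised 16 times in 72.7% of 66. A further 4 pairs that had not been raised were also called. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. Coordinates are 1-based on mm9.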

Results

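Contacts were mapped in fibroblasts from 2 mouse embryos of a 129xCast hybrid background, with 3 technical replicates per embryo, and analysed as 1 pooled map. The map held 1877655 recovered contacts between different bins after filtering. Of these, 1776055 joined different chromosomes and 101600 joined bins of the same chromosome. A kept bin had a median of 1651 contacts, with a range of 651 to 2805. A pair of bins on different chromosomes had a mean of 0.684 contacts, and 52.7% of such pairs had none. With 1 pooled map there were no replicates to compare.

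Same-chromosome contacts were barely more frequent than contacts between different chromosomes. They made up 5.41% of the balanced signal (95% interval 4.87 to 5.97, resampling chromosomes), against 5.26% in an even map. The share over that of an even map had a 95% interval of 1.02 to 1.04, resampling chromosomes. The ratio of same-chromosome to different-chromosome contact was 1.03. Recovered counts gave a share of 5.41% (exact binomial interval 5.38 to 5.44) and the same ratio of 1.03. If the map holds contacts between a Cast and a 129 end, this ratio compares homologous with non-homologous chromosomes. By chromosome, 11 of 20 had a Poisson interval above 1 and 0 had one below 1. The highest balanced ratios were those of chromosome 19 at 1.14, chromosome 17 at 1.09 and chromosome 7 at 1.07. The lowest were chromosome 8 at 0.992, chromosome 15 at 0.999 and chromosome 4 at 1.01. In recovered counts chromosome 15 had 1.02 (0.987 to 1.06), against 0.986 for chromosome 8 and 1.01 for chromosome 4. Without the bin filter the overall ratio was 1.09.

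On autosomes the ratio was highest at short distance and stayed slightly above 1 up to 49 Mb. Autosomal bins 1 Mb apart on the same chromosome had 1.47 times the expected contacts (95% Poisson interval 1.41 to 1.53, 2281 contacts). At 2 Mb the value was 1.17 (1.12 to 1.23), and at 3 Mb 1.08 (1.03 to 1.14). It was 1.06 (1.04 to 1.07) from 10 to 19 Mb and 1.03 (1.02 to 1.04) from 20 to 49 Mb, reached 1.00 (0.992 to 1.01) from 50 to 99 Mb and fell below 1 beyond 100 Mb, at 0.938 (0.919 to 0.958). Bins 1 Mb apart met more than expected on all 20 chromosomes, with an interval above 1 on 17 of them. Values in counts ranged from 1.16 on chromosome 19 to 1.97 on X. In the balanced signal they ranged from 1.16 on chromosome 10 to 2.29 on chromosome 7.

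Bins on different chromosomes whose coordinates differed by 1 Mb had a value of 1.03 (1.02 to 1.04). The same-chromosome value at 1 Mb was 1.43 times that (1.37 to 1.49). This ratio was 1.15 (1.10 to 1.21) at 2 Mb and 1.05 (0.995 to 1.10) at 3 Mb, where the interval reaches 1. It was 1.05 (1.01 to 1.09) from 4 to 5 Mb, 1.04 (1.02 to 1.05) from 10 to 19 Mb and 1.02 (1.01 to 1.03) from 20 to 49 Mb. From 50 to 99 Mb it was 1.01 (1.00 to 1.02), and beyond 100 Mb it was 0.985 (0.964 to 1.01). The slope of contact on distance over 2 to 50 Mb was shallow, at −0.0314 ± 0.0369 (SD over 19 autosomes). Over 1 to 20 Mb the mean slope was −0.0810, and without the bin filter it was −0.0795. The 1 Mb value in the balanced signal was 1.62, and 3.19 without the bin filter.

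**Figure D1:**
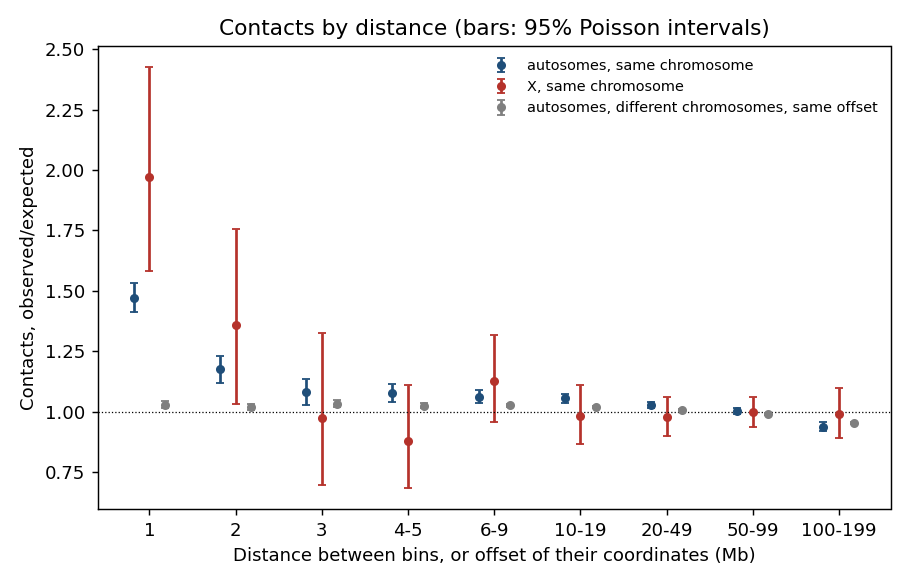
Observed/expected contacts (vertical axis, ratio of recovered counts) by distance in Mb (horizontal axis, classes) for autosomes and X within a chromosome, and for autosomes on different chromosomes by offset of coordinates. Points are ratios with 95% Poisson intervals; the same-chromosome value falls from 1.47 at 1 Mb to 1.00 at 50 to 99 Mb on autosomes, while different-chromosome pairs stay near 1, at 1.03 at 1 Mb.

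The series title concerns contacts between chromosomes, and these were close to even over the 190 chromosome pairs. Balanced observed/expected values ran from 0.969 to 1.04, with an SD of 0.0139. The highest pairs were chromosomes 16 and 19 at 1.04, 16 and 17 at 1.04, 12 and 18 at 1.03, 7 and X at 1.03, and 14 and 17 at 1.03. The lowest were 3 and 16 at 0.969, 2 and 19 at 0.969, 13 and 14 at 0.971, 6 and X at 0.973, and 3 and 19 at 0.973. With listed pairs alone, chromosomes 12 and 18 had 1.00, 13 and 14 had 0.993 and 3 and 16 had 0.990. Without the bin filter, 7 and X had 0.995, 13 and 14 had 0.996, 16 and 19 had 1.08 and 2 and 19 had 0.943. In a Poisson test on recovered counts, 14 pairs had an unadjusted p under 0.05, where 9.5 are expected by chance, and 0 passed Benjamini-Hochberg adjustment.

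In the main setting, contact between chromosomes fell weakly with their difference in length, but not beyond the spread between chromosomes. Pairs among the 5 shortest chromosomes (15 to 19) had a count ratio of 1.01 (95% Poisson interval 1.00 to 1.02). Pairs of a short with one of the 5 longest (1, 2, 3, 4 and X) had 0.992 (0.988 to 0.997), and pairs among the 5 longest had 1.00 (0.999 to 1.01). Over pairs, Pearson's r with the difference in log length was −0.184 and Spearman's rho −0.138. Of 10000 permutations of the chromosome labels, 0.08% gave a lower r and 1.12% a lower rho. With summed log length r was −0.127 and rho −0.0544, and 0% of permutations gave a lower r and 2.85% a lower rho. Expected values were fitted to each chromosome's total, which holds the relation to summed length near 0, so these shares cannot decide on it. The 95% jackknife spread over chromosomes was 0.186 for the r with length difference and 0.134 for that with summed length, so neither relation exceeded the spread between chromosomes. The r with the length difference was −0.183 in recovered counts, −0.107 with listed pairs alone and −0.0153 without the bin filter. In 100 simulated maps with no structure it ran from −0.122 to 0.141, a range that covers counting noise only.

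**Figure D2:**
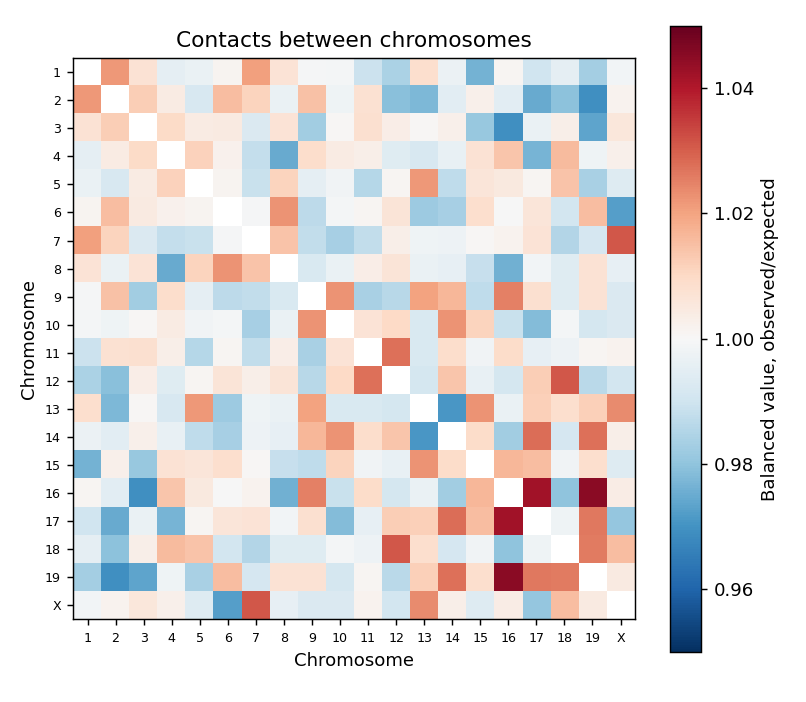
Balanced observed/expected (colour) for each pair of chromosomes 1 to 19 and X (both axes). Values span 0.969 for chromosomes 3 and 16 to 1.04 for chromosomes 16 and 19, and pairs among the shortest chromosomes lie mostly above 1.

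In the main setting X lay within the range of the autosomes in same-chromosome contact over its full length. Its balanced ratio was 1.01, against 1.04 ± 0.0351 (SD) over 19 autosomes, and 3 autosomes lay below it. Recovered counts gave 1.02 (95% Poisson interval 0.978 to 1.06, 2605 contacts). With listed pairs alone, X minus the autosomal mean turned from −0.0323 to 0.395. X had the fewest contacts per bin, and in that setting its trans level also rose, to 1.17 times the autosomal mean. The value of 0.395 therefore does not compare X with autosomes in contact frequency alone. At 1 Mb X had the highest value of the 20 chromosomes in counts, 1.97 (1.58 to 2.43, 89 contacts), which was 1.34 times the autosomal value (1.08 to 1.66). The interval of X overlaps that of chromosome 7, at 1.78 (1.51 to 2.09). In the balanced signal chromosomes 7 (2.29) and 12 (2.23) lay above X (2.16). From 20 to 49 Mb X had 0.979 (0.902 to 1.06).

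X carried the fewest contacts per bin with other chromosomes, 1219 per kept bin against 1540 ± 70.8 (SD) on autosomes. Coverage also removed 31.2% of its bins, against 7.54% on autosomes. Balancing brings the sums of all bins close together, so the balanced trans level of X, 0.995 times the mean, does not compare X with autosomes. The best division of X into a pair of domains lay at 54 Mb, with contacts 1.11 times as frequent within as across. That was the highest of the 20 chromosomes. On recovered counts it was 1.10, and 15 of 100 simulated maps with no structure gave X a value as high. The decay slope of X was −0.0604 in the balanced signal, with 5 autosomes below it, and −0.0780 in counts, with 1 below it. X minus the autosomal mean was −0.0291 in the main setting and −0.142 in a fit over 1 to 20 Mb. It was above 0 in a fit over 5 to 100 Mb (0.0373), with the stricter bin filter (0.00726) and without the bin filter (0.00602).

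Chromosome ends of the same kind met more than expected, and ends of unlike kind less. Mouse chromosomes are telocentric, so the low-coordinate end lies beside the centromere and the high-coordinate end beside the distal telomere. Within 10 Mb of the end, low-coordinate ends of different chromosomes had a balanced value of 1.11, high-coordinate ends 1.07 and unlike ends 0.943. The inner parts had 1.00. Counts gave 1.10 (95% Poisson interval 1.07 to 1.13), 1.07 (1.05 to 1.09) and 0.943 (0.928 to 0.959). The range over 10000 sets of random windows was 0.955 to 1.04 for windows of 1 set and 0.962 to 1.03 between sets, and all 3 values lay outside it.

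The excess rose toward the end. Low-coordinate bins under 5 Mb from the end met at 1.34 (1.22 to 1.47), those from 5 to 10 Mb at 1.08 (1.04 to 1.12) and those from 10 to 15 Mb at 1.03 (0.999 to 1.07). At the high-coordinate end the values were 1.10 (1.05 to 1.14), 1.05 (1.01 to 1.08) and 1.04 (1.01 to 1.08). Under 5 Mb from the end, 34 low-coordinate and 81 high-coordinate bins were kept, so these bands are not matched. Further in, low-coordinate bands of 5 Mb from 15 to 50 Mb stayed at 1.02 to 1.05, and high-coordinate bands at 0.982 to 1.02. On each side 19 of 20 chromosomes had a value above 1. The interval lay above 1 on 11 chromosomes at the low-coordinate end and 9 at the high-coordinate end. Each contact counts for both of its chromosomes, so the values of the chromosomes overlap and are not separate observations. The values below 1 were those of chromosome 14 at the low-coordinate end, with 1 kept bin and 0.828 (0.602 to 1.11), and chromosome 19 at the high-coordinate end, with 0.943 (0.875 to 1.01). With listed pairs alone the high-coordinate value was 0.958, and with no bin filter the low-coordinate value was 1.06.

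**Figure D3:**
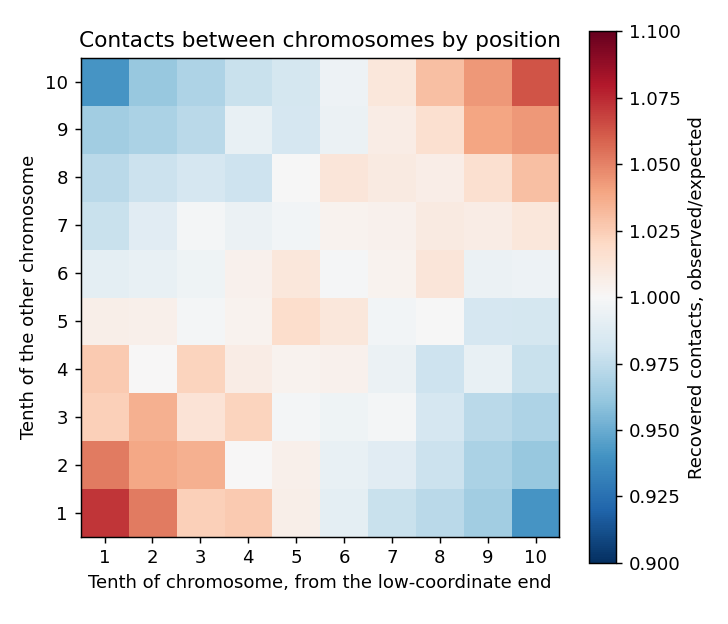
Observed/expected recovered contacts between different chromosomes (colour) by position along each chromosome in 10 equal parts, part 1 being the low-coordinate end (both axes). The value is 1.07 between low-coordinate parts and 0.941 between opposite ends.

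Chromosomes 12, 15, 16, 18 and 19, which carry ribosomal DNA in laboratory mice, showed little preference for one another. Their 10 pairs had a mean balanced value of 1.01, against 1.00 for other autosome pairs, a difference of 0.00811. This lay at percentile 96.8 of all 11628 sets of 5 autosomes. Adjusted for chromosome length the difference was 0.00203, at percentile 69.5. Summed counts of these pairs gave 1.01 (95% Poisson interval 0.997 to 1.01). Which of these chromosomes carry ribosomal DNA in 129 or Cast is not in the labels.

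Trans contact profiles separated the bins into 2 classes along a first eigenvector, as a compartment analysis does. The first eigenvalue was 8.53 and the second 4.55. Scores of neighbouring bins correlated at 0.508, whereas 100 simulated maps with no structure gave −0.0522 to 0.0532. Class 1, the class with the higher mean balanced trans value (0.593 against 0.590), held 978 bins and class 2 held 1363. Balancing brings bin sums close together, so this order names the classes and does not mark class 1 as rich in trans contacts. The sign was not set by genes, so neither class is called active.

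Bins of like score met more often. In counts, bins of the highest score quintile met each other at 1.20 (95% Poisson interval 1.19 to 1.20), those of the lowest at 1.09 (1.08 to 1.10), and bins of these quintiles met across at 0.874 (0.869 to 0.879). The strength, within over across, was 1.34 in the balanced signal. Since the score comes from the same contacts, each contact was also assigned at random to one of 2 parts, a step chosen after seeing the data. With the score from one part and the contacts from the other, the strength was 1.17, against 0.992 to 1.01 in 20 simulated maps. A score from same-chromosome contacts alone gave 0.999.

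In the balanced signal class 1 took the largest share of bins on chromosome 11 at 50.4%, followed by chromosome 19 at 50% and chromosome 10 at 46.8%. In counts chromosome 19 came first at 51.9%, ahead of chromosome 11 at 49.6%. It took the smallest on X at 28.2%, chromosome 7 at 33.6% and chromosome 3 at 38.5%. Chromosomes 11 and 19 are known as gene-dense mouse chromosomes, but gene density was not tested here. The ranking therefore gives no sign to the classes. Without the bin filter, neighbouring scores correlated at 0.0108. With listed pairs alone they correlated at 0.300, and the strength was 1.09.

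**Figure D4:**
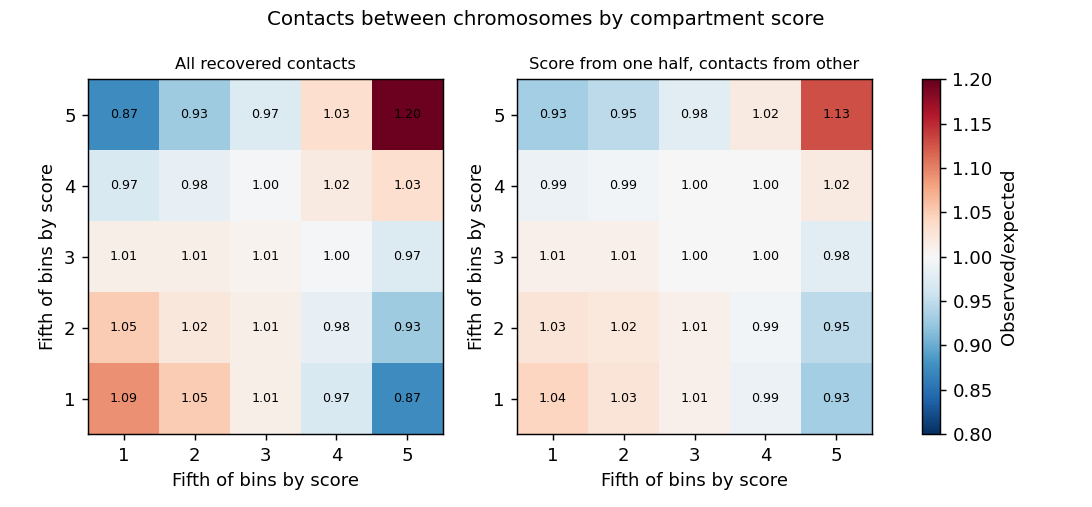
Observed/expected contacts between different chromosomes by quintile of the compartment score (both axes, 5 highest), for all recovered contacts (left) and with score and contacts from separate random parts (right). The highest quintile met itself at 1.20 on the left and 1.13 on the right.

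Single pairs of bins on different chromosomes rarely rose above counting noise. Of 2594953 pairs, 2 passed the adjusted threshold of 0.05 in the 1-sided Poisson test, and 71507 (2.76%) had an unadjusted p under 0.05. That share is below the threshold itself, so it shows no surplus of low values. The first pair joined chromosome 7 from 3000001 to 4000000 with chromosome 14 from 19000001 to 20000000. In the exact Poisson test it had 8 contacts where 0.225 were expected (adjusted p = 0.000352). The second, outside the rule for named pairs and chosen after its values were seen, joined chromosome 1 from 115000001 to 116000000 with chromosome 18 from 86000001 to 87000000. In the exact Poisson test it had 10 contacts where 0.746 were expected (adjusted p = 0.00975). With the stricter bin filter 1 pair passed. The chromosome 7 bin of the first pair lies near the low-coordinate end of its chromosome, where misplaced repeat reads remain open. Whether such reads gave the contacts of either called pair was not tested.

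The 10 named pairs, with the highest balanced observed/expected, ran from 17.8 to 35.1 on 3 to 8 contacts, and 1 of them passed. In all 10, at least one bin lay below the 5th percentile of contacts. After the pair of chromosomes 7 and 14, the next was chromosome 12 from 21000001 to 22000000 with chromosome 15 from 103000001 to 103494974, on 3 contacts. Mean trans contact lay between 0.913 and 1.05 times the genome mean for 95% of kept bins, and the lowest bin had 0.0189. The 10 highest bins lay at 1.06 to 1.09 times the genome mean, the first on chromosome 4 from 132000001 to 133000000. Balancing brings bin sums close together, so this range and order are what it leaves and do not mark bins rich in trans contacts. These 10 bins had 768 to 1679 contacts.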

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

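The tests of offset, of the outer 5 Mb, of counting noise, of bin coverage and of position along the chromosome for the score were chosen after the results were seen, as was the estimate for wrongly assigned alleles. The test of the outer 5 Mb was set first against 1 and then, once the values were known, against bands of like position, and the latter form is the one kept. The labels give 1 group, so no biological difference between groups was tested.

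Contacts with both ends in 1 bin were not used in the comparisons, and the table held 2884 of them. On autosomes 2673 such contacts lay in kept bins, which was 3.26 times the expected number (95% Poisson interval 3.14 to 3.38) if a bin pairs with itself at 50% of the product of its factors. Against the full product it was 1.63 (1.57 to 1.69). A further 77869 contacts had an end in a bin left out for low coverage, and these bins had a median of 353.5 contacts.

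The same-chromosome excess at short distance was weighed against 3 technical explanations. Positions that meet on any pair of chromosomes leave a ratio of 1.43 at 1 Mb (95% interval 1.37 to 1.49), which argues against position alone. Where both bins lay above the median of contacts, the value was still 1.39 (1.31 to 1.48), which argues against poorly covered bins. Contacts of a single allele with an end assigned to the wrong allele remain open. The excess from 1 to 9 Mb is 0.0926% of all contacts, so rare wrong assignments could give it, and they cannot be told apart from contacts between homologs because only the pooled table was used here.

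The excess between chromosome ends of the same kind was weighed against coverage, repeats and compartment class. Among 10000 sets of inner windows of like coverage the highest value was 1.04, below the low-coordinate value of 1.10 in counts. Misplaced repeat reads in the outermost bins remain open. Bins 5 to 10 Mb from the low-coordinate end had 1.08 (1.04 to 1.12), but bands of like position from 10 to 50 Mb had 1.03 together. The ratio of these was 1.05, with a 95% Poisson interval of 1.01 to 1.09 and a jackknife interval over chromosomes of 0.973 to 1.12, which reaches 1. Set against what the score quintiles predict, low-coordinate ends stood at 1.10 (1.07 to 1.13) and high-coordinate ends at 1.07 (1.05 to 1.09), with intervals for counting error only. Coverage and misplaced repeat reads were not tested for the high-coordinate ends. Mapping bias that extends beyond 5 Mb from the end was not tested.

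The 2 classes of bins were weighed against noise, coverage and position. The highest neighbour correlation in 100 simulated maps was 0.0532, far below 0.508. The score correlated with the bin factor at −0.0669, but it comes from profiles with the bin factors divided out, so this cannot decide on coverage. The decile of the chromosome explained 1.43% of its variance. The values for noise and position argue against those explanations as the whole cause, while coverage remains open. Base composition and the density of sequence differences between strains were not tested and may contribute.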

How the results depend on the processing

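The setting without bins held by a single value, the 5 to 10 Mb windows and the random split of contacts were chosen after seeing the data. Of 118 values recomputed under other settings, 93 stayed within the spread over chromosomes, 22 moved beyond it and 3 reversed. Called pairs of bins, which are among these, have no such spread and were judged by the change in their number. The cause was not tested except where stated. Of 60 further values for the 10 named chromosome pairs, judged by the width of their Poisson intervals, 53 stayed, 6 moved and 1 reversed. Without the bin filter, which lets bins with 1 contact enter, the same-chromosome share was 5.69%, its ratio to different-chromosome contact 1.09, the decay slope −0.0795, the 1 Mb value 3.19, the low-coordinate end value 1.06, the neighbour correlation of scores 0.0108, and the pair of chromosomes 7 and X reversed to 0.995. Listed pairs alone drop every zero, so their means also depend on coverage. With these the ratio was 1.02, X minus autosomes 0.395, the X trans level 1.17, the high-coordinate ends reversed to 0.958, compartment strength 1.09 and neighbour correlation 0.300. The stricter filter gave a 1 Mb value of 1.41, an X trans level of 0.987 and 1 called pair of bins. Recovered counts gave an X trans level of 0.791, which is contacts per bin and so another quantity. Without bins held by a single value it was 1.00. A fit over 1 to 20 Mb gave a decay slope of −0.0810 and X minus autosomes −0.142. Low-coordinate ends of 5 Mb gave 1.42. A score from same-chromosome contacts gave a strength of 0.999 and a neighbour correlation of 0.00482, the second eigenvector 0.996 and 0.0310, and the random split of contacts a strength of 1.17. Leaving out each chromosome in turn, the share ranged from 5.61% to 5.73%, since fewer chromosomes raise the share of an even map, and called pairs of bins from 1 to 3; the count was 1 without chromosome 1, 7, 14 or 18, which carry the called pairs. The other results stayed within their spread. That spread is at least as wide as the jackknife spread computed from these same values. Staying within it was therefore close to fixed in advance and does not show that no chromosome matters. Scaling each allele's map, thinning gene lists, and balanced, listed-only or capped values for called pairs could not be run. Depth limits single pairs of bins, with a median expected count of 0.679.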

Other observations

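The tests here were chosen after the data were seen. Contacts between different chromosomes had a value of 1.07 within the first decile of the chromosomes, 1.01 between the first and the fifth decile and 0.941 between the first and the last. Among deciles 4 to 7 the values ran from 0.994 to 1.02. No interval was computed for these values. On autosomes, same-chromosome contacts beyond 100 Mb (0.938) lay close to different-chromosome contacts at the same offset (0.953).

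The longest run of bins in the highest score quintile covered chromosome 9 from 56000001 to 67000000, 11 bins in all. The next longest were chromosome 1 from 88000001 to 96000000 with 8 bins, chromosome 4 from 132000001 to 139000000 with 7 and chromosome 5 from 30000001 to 37000000 with 7. In the lowest quintile the longest run was chromosome 1 from 22000001 to 28000000, with 6 bins. These regions were chosen after their values were seen.

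The sex of the embryos is not in the labels. One hypothesis is that a second X was present in much of the pool. With a single X in every nucleus, contacts between a Cast X and a 129 X could not form, and far same-chromosome values would lie well below 1. X bins 20 Mb or more apart had 0.991 times the expected contacts (95% Poisson interval 0.947 to 1.04, 1937 contacts), which argues against a single X throughout. This rests on the reading that the map holds contacts between unlike alleles.

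Balancing gave very large values to bins with 1 contact. The bin on chromosome 1 from 85000001 to 86000000 had 1 contact, with chromosome 15 from 72000001 to 73000000, and a balanced value of 1500. That value filled 98.0% of the row of the chromosome 15 bin, which had 2118 contacts, and left it a mean of 0.0128 per other kept bin. The same held for chromosome 18 from 77000001 to 78000000, partnered with chromosome 7, and for X from 75000001 to 76000000, partnered with chromosome 14. Of the pairs with values above 100, all 107 involved a bin that the coverage filter left out.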
